A study of Escherichia coli with 9 samples.

How the data were processed

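RNA was sequenced from Escherichia coli DH5α grown in LB at 37 °C and held for 2 h with triclosan at 0, 20 µg/L or 2 mg/L, in 3 libraries per condition, on an Illumina HiSeq per the labels. The data used are the authors' deposited table, with 1 row for each of 4676 loci of a draft genome. Per the file headers it holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for each library, as the authors computed it. The authors also deposited mean FPKM, a log2 fold change and a q-value for all triclosan libraries against control, per the file headers. Cufflinks 2.2.1 is named in the submitters' processing notes. The aligner, read filters, genome build, library strandedness and mapped read totals are not given in the sources used here. Without strand, reads from overlapping or antisense genes cannot be told apart, and 37 of the 127 named genes share their listed interval with another locus. Genes with near-identical copies are uncertain in the same way.

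Most loci carry only a locus tag and a product name. Symbols were taken from the gene column (175 loci), from a protein name in the product text where the coding length equalled that of the gene of that name in the K-12 MG1655 reference (assembly ASM584v2, 876 loci), or from the product's function with equal coding length (1932 loci), and 1693 loci stayed without a symbol. Of the names with a named neighbour on their contig, 172 of 174 from the gene column, 874 of 875 from product text and 1930 of 1931 from function lay within 10 genes of such a neighbour in the reference order. The 4 that did not were dropped, so 2979 named loci were used. Of the 657 genes in the fixed lists, 605 were matched, 1 of them wrongly: dprA of the DNA uptake list went through an older synonym to nfsB, a nitroreductase gene. The list is given as matched. Without nfsB, or with smf, the homologue of DprA, in its place, it passed in no comparison (lowest adjusted p = 0.44), and no other list gained or lost its call. Positions are those of the deposited table, counted from 1.

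The table gives no counts. The steps between low FPKM values of genes longer than 600 nt showed the FPKM of 1 fragment, and with it every low value tested was a whole number of fragments within 0.1. On this basis the 2807 genes longer than 600 nt held 1429986, 1455623 and 1327918 fragments in control replicates 1 to 3, 1878881, 1607704 and 1481375 at 20 µg/L, and 1727245, 1371436 and 1696321 at 2 mg/L. In a gene of 1 kb, 1 fragment was worth 0.51 to 0.814 FPKM, and 8.59% to 14.7% of these genes had fewer than 10 fragments. In shorter genes 1 fragment is worth far more, so values of genes under 300 nt rest on few fragments for their FPKM, and fragments of PCR origin are not independent molecules. The mean fragment length that fitted was 179 to 197 nt in all libraries.

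FPKM values were used as deposited, with no further scaling. Median-of-ratios factors lay between 0.988 and 1.03. Genes with a mean of at least 1 FPKM in 1 or more conditions were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided), all 9 libraries in 1 fit with 6 residual degrees of freedom, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were each dose against control and 2 mg/L against 20 µg/L. Of 22 gene lists fixed in advance, the 21 with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison, and again with the correlation estimated for each list. The remaining list, of structural RNA genes, had too few genes with values. Counts of list members are given adjusted over all genes and adjusted over the list alone. Named genes are the 12 with the largest increase and the 12 with the largest decrease in each comparison, among those that passed, with separate libraries and a mean of at least 5 FPKM, plus a fixed panel of 21 genes and up to 4 members of each list described. Genes named outside this rule, unnamed loci among them, were chosen after their values were seen. Tables were prepared with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6) and drawn with matplotlib 3.10.9.

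The test was tested on simulated data in which each gene kept its control mean and its own spread, with 200 genes changed per dose and the ribosomal protein list moved as a whole. For 20 µg/L against control it called 66% of genes changed by a log2 fold of 1 and 97% of those changed by 2, for 2 mg/L against control 70.7% and 88%, and for the doses against each other 70.4% and 92.6%. Calls with no true change made up 6.4%, 2.47% and 4% of the calls in the same order. The moved list was called each time and no other list was. In this simulation genes varied independently and with the same spread in every condition. It therefore cannot show how often lists of genes that vary together are called without a change. Its shares of calls may also differ where the conditions differ in spread.

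The alternatives fixed in advance were median-of-ratios scaling, quantile normalization, limma without the trend, no filter or a mean of 5 FPKM, a pseudocount of 0.1 or 5, fits with only the compared conditions, the replicate number as a block, stricter thresholds, the estimated list correlation and leaving out each library. Added later were limma voom on the recovered fragments of genes over 600 nt, the same genes as log2(FPKM + 1), removal of each library's trend over coding length, the 2 mg/L libraries averaged into 1 sample, and the DNA uptake list without nfsB or with smf in its place. The authors' own q-values pool the doses and so gave no alternative for a single dose.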

Results

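The transcriptome of Escherichia coli DH5α, a laboratory cloning strain of the K-12 lineage, was measured after exposure to triclosan, a biocide known to inhibit the enoyl-ACP reductase FabI of fatty acid synthesis. Cells were grown in LB broth at 37 °C without shaking and exposed for 2 h to no triclosan, to 20 µg/L or to 2 mg/L. Each condition had 3 libraries, 9 in all. FPKM was given for 4676 loci. Of these, 4409 had a mean of at least 1 FPKM in at least 1 condition and were tested. The libraries held 1327918 to 1878881 fragments on genes longer than 600 nt, with a median of 97 to 157 fragments per gene. The labels do not say whether the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Within a condition the libraries correlated across genes at 0.902 to 0.922 in the control, 0.936 to 0.937 at 20 µg/L and 0.924 to 0.942 at 2 mg/L. Control replicate 2 stood apart from the other control libraries. On fragments of genes over 600 nt its chi-square per degree of freedom was 14.8 against replicate 1 and 14.1 against replicate 3. Between control replicates 1 and 3 it was 6.45. Values are mean FPKM ± SD with n = 3. Fold changes are log2 ± SE on the log2(FPKM + 1) scale, which understates the change of low genes.

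The lower dose was compared with the control to find which genes respond to 20 µg/L. The genes of colanic acid, a capsular exopolysaccharide, fell together. The tyrosine phosphatase gene wzb fell from 133 ± 14.8 to 18.4 ± 6.41 FPKM (log2 fold change -2.83 ± 0.26, adjusted p = 8.0e-04) and the tyrosine kinase gene wzc from 104 ± 7.13 to 19 ± 3.04 FPKM (log2 fold change -2.40 ± 0.14). The GDP-fucose synthesis gene gmd fell from 390.3 ± 30.1 to 73.4 ± 7.94 FPKM. Its neighbour fcl fell from 268 ± 18.4 to 63.6 ± 6.11 FPKM, and the glycosyltransferase gene wcaC from 70.3 ± 2.93 to 12.2 ± 2.13 FPKM. The GDP-mannose genes cpsB and cpsG had log2 fold changes of -2.38 ± 0.17 and -2.30 ± 0.14. The values were -2.14 ± 0.16 for wcaE, and for wcaB -2.08 ± 0.17, gmm -2.09 ± 0.12 and wcaA -1.92 ± 0.15. The named genes from wzb to wcaJ lie on contig 5 of the draft assembly, between positions 34093 and 50031. An unnamed lipoprotein locus next to wzb, NJ74_RS03910, had a log2 fold change of -2.33 ± 0.15.

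**Figure D1:**
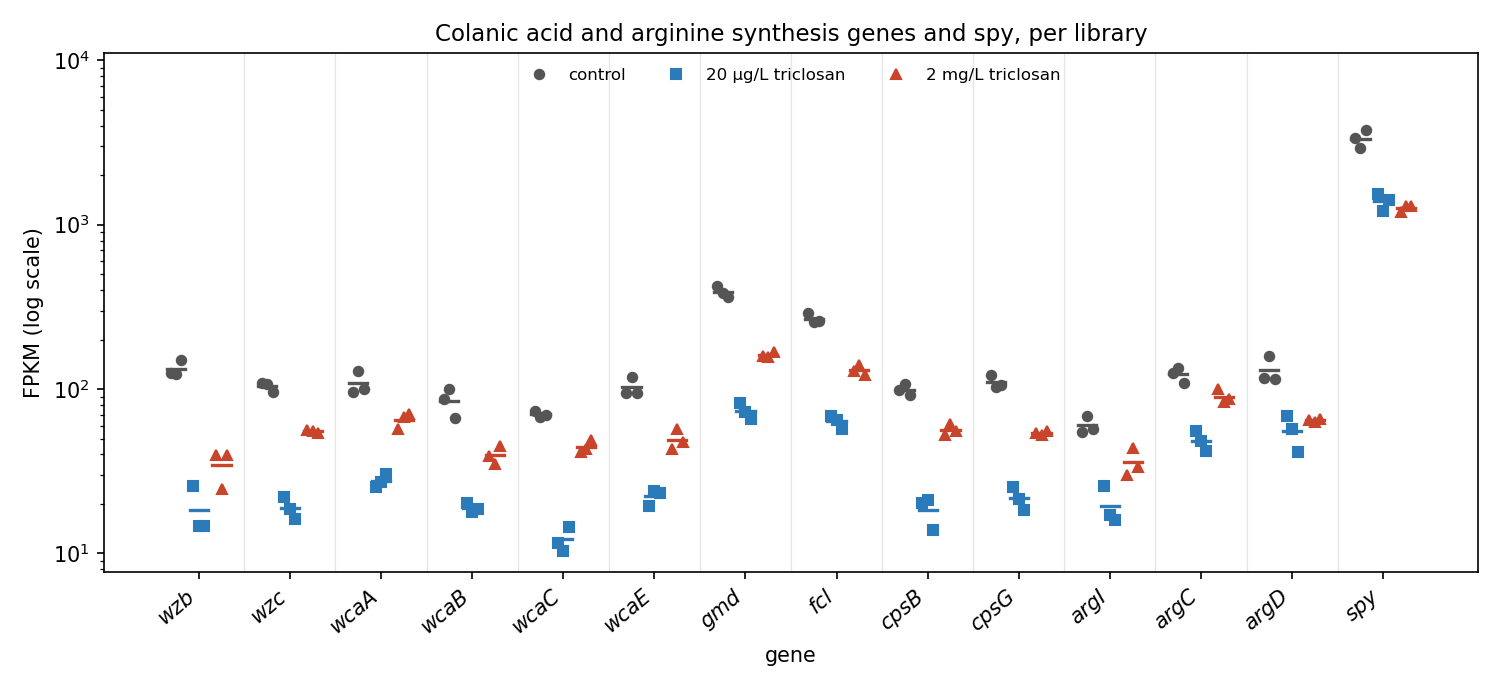
FPKM of 14 genes on a log axis, with a point for each of the 9 libraries and a bar at the mean of each condition. For every gene drawn, the 3 libraries at 20 µg/L lie below the 3 control libraries, as for gmd at 73.4 against 390.3 FPKM.

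The arginine synthesis genes argI, argC, argD, argB, argG and argH also fell at 20 µg/L. The ornithine carbamoyltransferase gene argI went from 60.3 ± 7.63 to 19.6 ± 5.23 FPKM (log2 fold change -1.60 ± 0.22, adjusted p = 0.00959). The genes argC, argD, argB, argG and argH had log2 fold changes of -1.32, -1.22, -1.10, -0.74 and -0.70, while argA, argE, carA and carB did not pass. The periplasmic chaperone gene spy fell from 3334 ± 420.3 to 1386 ± 169 FPKM. The putrescine importer gene plaP measured 184 ± 8.81 FPKM in the control and 79.5 ± 5.69 FPKM at 20 µg/L. The phosphate uptake genes pstS and pstB had log2 fold changes of -0.56 and -0.53. For galU and galF, which act in UDP-glucose synthesis, they were -0.56 and -0.40. The efflux pump gene mdfA (-1.19 ± 0.22), the enterobactin exporter gene entS (-0.95 ± 0.17), rutB of uracil breakdown (-1.97 ± 0.36) and wcaF (-2.22 ± 0.35) passed as well. Of the named genes that rose, the lysine-cadaverine antiporter gene cadB went from 113 ± 13.3 to 211 ± 45.7 FPKM, the galactitol transport gene gatA from 1340 ± 71.2 to 2163 ± 349.8 FPKM, and ydfG from 351 ± 15.8 to 454 ± 5.15 FPKM. An unnamed locus of 237 nt, NJ74_RS19865, had a log2 fold change of 1.05 ± 0.13. The locus NJ74_RS10640, of 174 nt and annotated as a periplasmic protein, was listed at 0 in every control library and at 50.5 ± 10.8 FPKM. It is shorter than the mean fragment fitted in any library (179 to 197 nt), so its FPKM may rest on few fragments.

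In limma's test, 55 of the 4409 genes passed an adjusted p of 0.05, 5 higher and 50 lower, and 653 had an unadjusted p under 0.05. In all 55 the libraries of the conditions did not overlap, which a low p from the same libraries nearly requires, so it adds no separate support. Over all genes the share was 16.5%, where chance gives 10%. The count of genes that passed was 36 without control replicate 1 and 34 without 2 mg/L replicate 1, and 31 when only the compared libraries entered the fit. It was 62 without control replicate 3. Of the 55 themselves, 31, 34, 28 and 40 passed in these fits, in the same order. The arginine genes, plaP, pstS, pstB, galU and galF lie outside the fixed rule for named genes. Whether each of their calls held in these fits is not given here. On genes over 600 nt, 104 passed on fragments (26 higher and 78 lower) and 96 on FPKM (16 higher and 80 lower). The 5 higher genes became 2 without 2 mg/L replicate 1 and 13 without control replicate 3. The calls of cadB, rutB, mdfA and entS ended whichever library was left out, with adjusted p up to 0.11, 0.127, 0.133 and 0.112. Those of gatA, ydfG and wcaF ended without 6, 8 and 5 of the libraries, with adjusted p up to 0.0971, 0.136 and 0.0868. All 7 also ended with the 2 mg/L libraries averaged as 1 sample (adjusted p up to 0.237, in cadB).

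Among the fixed gene lists, iron uptake genes stood lower at 20 µg/L, with a median log2 fold change of -0.41 over 34 genes and 29 of them below 0 (camera adjusted p = 1.4e-07, and 0.0113 with an estimated correlation). Of these only entS passed over all genes, and 7 passed when adjusted over the list alone. The enterobactin synthesis genes entC and entB had log2 fold changes of -1.67 ± 0.34 and -1.23 ± 0.27, and exbD of the TonB system -0.41 ± 0.10. On genes over 600 nt entC and entB passed (adjusted p = 0.00264 and 0.0354 on fragments), and entC did so without 20 µg/L replicate 3 (0.0423) and with a pseudocount of 5 (0.0476). Iron uptake was the only list to pass at this dose with an estimated correlation. In all, 6 lists passed at this dose with the preset correlation. Of the 10 ways to split these 6 libraries, 5, the real one among them, called at least as many lists, and the highest called 10. The number of lists called at 20 µg/L therefore does not set the real grouping apart. The list of fimbriae, curli and exopolysaccharide was lower (adjusted p = 9.7e-06, and adjusted p = 0.0915 with an estimated correlation). Its 9 called members out of 31 were all colanic acid genes. When adjusted over the list alone 9 lower and 1 higher member passed, and the median of the list was -0.08. The multidrug efflux list was lower (median -0.16, adjusted p = 0.00778, and adjusted p = 0.257 with an estimated correlation). In it mdfA was the 1 gene called over all genes, and 3 passed when adjusted over the list alone. The genes mdtA, mdtB and bcr had log2 fold changes of -0.64, -0.64 and -0.47, and on genes over 600 nt mdtA and mdtB passed (adjusted p = 0.0313 and 0.00364 on fragments, 0.0442 and 0.0336 on FPKM). Without 20 µg/L replicate 3 the call of the efflux list ended (adjusted p = 0.0667).

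Fatty acid degradation genes stood higher at 20 µg/L, 9 of 10 above 0 with a median of 0.39 (camera adjusted p = 4.1e-05, and adjusted p = 0.411 with an estimated correlation). None passed over all genes and 8 passed when adjusted over the list alone. The log2 fold changes were 0.67 ± 0.19 for fadB, 0.70 ± 0.21 for fadA, 0.43 ± 0.12 for fadD and 0.37 ± 0.11 for fadJ. On genes over 600 nt fadB and fadA passed on fragments (adjusted p = 0.0155 and 0.0146) and on FPKM (0.0415 and 0.0419), and fadD on fragments alone (0.041). Acid resistance genes had a median of 0.28 (adjusted p = 3.7e-04, and adjusted p = 0.366 with an estimated correlation), with cadB called over all genes and 3 called when adjusted over the list alone. Here the lysine decarboxylase gene cadA had a log2 fold change of 0.66 ± 0.14, the arginine decarboxylase gene adiA 0.86 ± 0.26 and hdeD 0.31 ± 0.11. Both decarboxylase genes passed without control replicate 3 (adjusted p = 0.0478 for cadA and 0.0013 for adiA) and on genes over 600 nt (0.00392 and 0.0142 on fragments). Genes of aerobic respiration, the TCA cycle and ATP synthase had a median of 0.13 over 43 genes, none called by itself in either adjustment (adjusted p = 0.00316, and adjusted p = 0.871 with an estimated correlation). The log2 fold changes of gltA, nuoK, nuoJ and atpI were 0.40, 0.43, 0.30 and -0.34. The call of this list ended without control replicate 2 (adjusted p = 0.378), without 20 µg/L replicate 1 (adjusted p = 0.0502) and under quantile normalization (adjusted p = 0.407).

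The genes of triclosan's known target pathway did not pass at 20 µg/L. The target gene fabI measured 1170 ± 366 FPKM in the control and 1366 ± 142 FPKM at 20 µg/L (log2 fold change 0.27 ± 0.21, adjusted p = 0.592). For fabA and fabB the log2 fold changes were 0.11 ± 0.10 and 0.06 ± 0.11. The list of fatty acid synthesis had a median of -0.02 over 14 genes (adjusted p = 0.718) and phospholipid synthesis 0.04. Of the other fixed genes, marA, acrB, tolC and soxS had log2 fold changes of -0.60, -0.27, 0.24 and -0.13. For katG and ahpC they were -0.22 and 0.37, and for recA, lexA and umuD 0.15, 0.32 and -0.33. For ompF, ompC and ompA the values were 0.15, 0.23 and 0.11, for cpxP and pspA 0.27 and 0.01, and for gadE and rpoS 0.04 and 0.20, with no adjusted p below 0.247 among them. The lists of lipid A and LPS core, outer membrane proteins, oxidative stress, SOS response, heat shock, envelope stress and general stress did not pass, with medians of 0.02, 0.08, 0.11, 0.13, 0.03, 0.09 and 0.20. Nor did flagella and chemotaxis, DNA uptake homologues, ribosomal proteins, anaerobic respiration, amino acid biosynthesis and toxin-antitoxin genes, with medians of 0.03, 0.06, -0.02, 0.13, 0.15 and -0.04. The DNA uptake list includes nfsB, matched to it in error, and had the same median of 0.06 without it. In the heat shock, flagella, ribosomal protein and toxin-antitoxin lists the median, mean and test differed in sign.

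The higher dose was compared with the control in the same way. At 2 mg/L, genes of flagella and chemotaxis rose together: 27 of 46 passed over all genes and 27 when adjusted over the list alone, all of them higher. The list had a median of 1.32 (camera adjusted p = 4.4e-10, and 0.00406 with an estimated correlation). It was the only list to pass against the control at this dose with an estimated correlation. The hook gene flgE rose from 9.41 ± 3.1 to 53 ± 5.64 FPKM (log2 fold change 2.42 ± 0.25, adjusted p = 1.9e-04), the flagellin gene fliC from 79 ± 5.05 to 192 ± 3.83 FPKM (1.27 ± 0.11). The genes flgD and flgG had log2 fold changes of 2.14 ± 0.27 and 1.82 ± 0.23. The flagellar master regulator gene flhD and the flagellar sigma factor gene fliA had log2 fold changes of 1.97 ± 0.36 and 1.95 ± 0.33.

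Genes for tryptophan synthesis, sulfate uptake and the glyoxylate bypass were among the named genes with the largest decreases at 2 mg/L. The anthranilate synthase gene trpE fell from 891 ± 156 to 76 ± 9.1 FPKM (log2 fold change -3.53 ± 0.17, adjusted p = 7.1e-06). The next gene, trpD, fell from 474 ± 109 to 50.6 ± 2.71 FPKM and the tryptophan transporter gene mtr from 4234 ± 520.3 to 390.1 ± 17.7 FPKM. The sulfate uptake genes cysA and sbp had log2 fold changes of -3.01 ± 0.12 and -3.09 ± 0.16. For cysP and cysH they were -2.14 ± 0.08 and -2.83 ± 0.17, and for thrA of threonine synthesis -2.84 ± 0.13. The isocitrate lyase gene aceA went from 1582 ± 234 to 157 ± 6.11 FPKM and the malate synthase gene aceB from 1979 ± 389 to 253 ± 10.7 FPKM. The largest decrease among named genes under the fixed rule was that of zraP, a zinc-associated periplasmic protein, from 541 ± 255 to 33.6 ± 12.2 FPKM (-3.92 ± 0.44). The carbon starvation gene cstA fell from 4194 ± 742 to 382 ± 17.6 FPKM and the proline symporter gene putP from 1275 ± 172 to 149.6 ± 5.41 FPKM. Amino acid biosynthesis genes stood lower as a list, with 30 of 62 lower and 7 higher over all genes, and 32 and 10 when adjusted over the list alone. The list passed (median -0.37, adjusted p = 1.0e-05, and adjusted p = 0.31 with an estimated correlation). The members that rose included the leucine synthesis genes leuA, leuB, leuC and leuD, at 1.93, 1.64, 1.37 and 1.10.

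**Figure D2:**
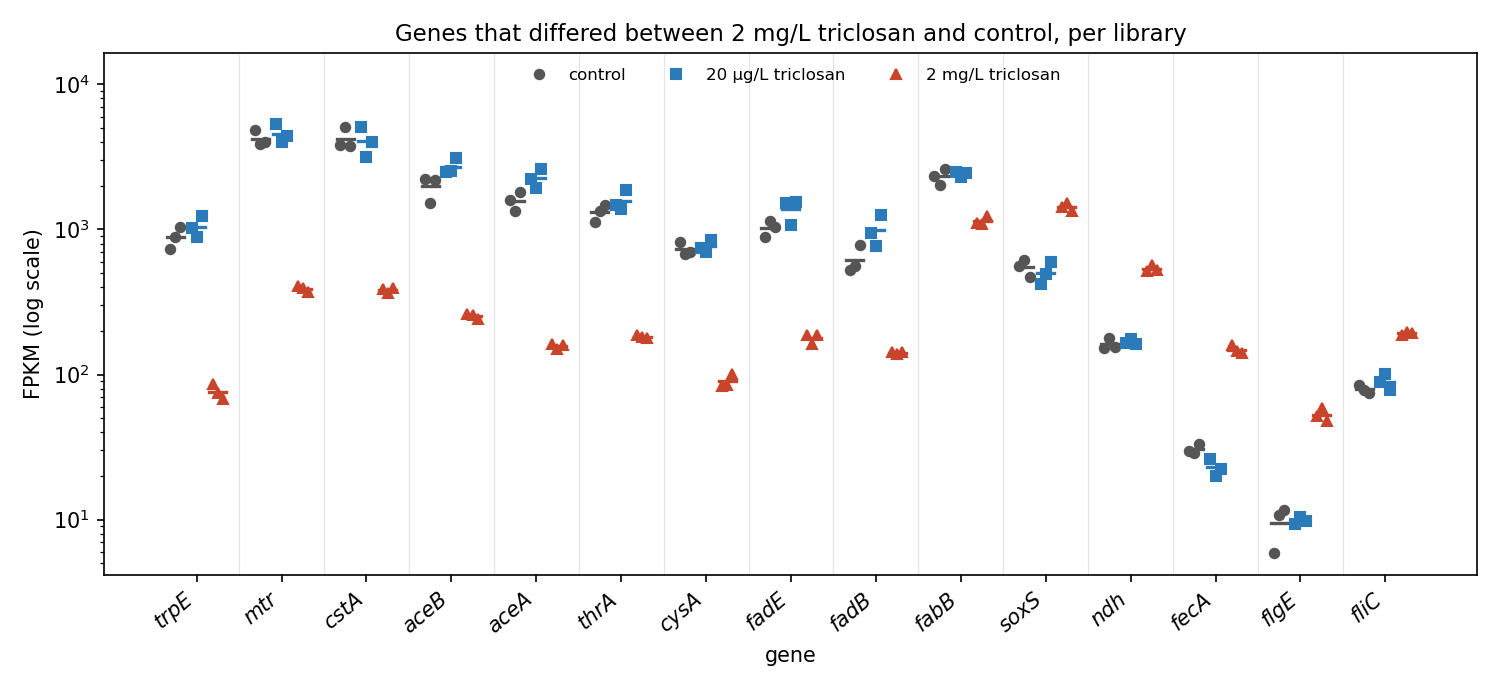
FPKM of 15 genes on a log axis, with a point for each of the 9 libraries and a bar at the mean of each condition. For every gene drawn, the 3 libraries at 2 mg/L lie wholly above or wholly below the 3 control libraries, as for trpE at 76 against 891 FPKM and ndh at 537 against 162 FPKM.

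Fatty acid degradation genes fell at 2 mg/L, 8 of 10 over all genes and 8 when adjusted over the list alone (list median -1.67, adjusted p = 6.4e-06, and adjusted p = 0.31 with an estimated correlation). The acyl-CoA dehydrogenase gene fadE went from 1030 ± 129 to 179 ± 14.1 FPKM, fadB from 621 ± 136 to 142 ± 3.37 FPKM. The genes fadD and fadJ had log2 fold changes of -1.67 ± 0.12 and -1.70 ± 0.11. In fatty acid synthesis, fabB, which encodes 3-oxoacyl-ACP synthase I, fell from 2328 ± 291 to 1145 ± 82.7 FPKM (-1.02 ± 0.11, adjusted p = 2.1e-04). The target gene fabI measured 751 ± 53.3 FPKM against 1170 ± 366 FPKM in the control and did not pass (-0.59 ± 0.21, adjusted p = 0.0649), nor did fabA (0.04 ± 0.10), which passed under quantile normalization at 0.27 (adjusted p = 0.0334). The change of fabI passed without control replicate 2 (log2 fold change -0.84, adjusted p = 0.0033) and on genes over 600 nt (adjusted p = 0.00496 on fragments and 0.0159 on FPKM). Over the fatty acid synthesis list, 1 gene was higher and 4 were lower, 1 and 5 when adjusted over the list alone, and the list did not pass (median -0.11, adjusted p = 0.239).

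Respiratory genes moved in both directions at 2 mg/L. The succinate dehydrogenase genes sdhA and sdhB had log2 fold changes of -1.68 ± 0.12 and -1.68 ± 0.19. The citrate synthase gene gltA had -1.20 ± 0.13. The NADH dehydrogenase II gene ndh rose from 162 ± 14.8 to 537 ± 29.8 FPKM (1.73 ± 0.09). Of the 43 aerobic respiration genes 16 were lower and 2 higher over all genes, 18 and 4 when adjusted over the list alone. The list was lower (median -0.25, adjusted p = 0.00566, and adjusted p = 0.683 with an estimated correlation). The call of that list ended without control replicate 1 (adjusted p = 0.0761) and under quantile normalization (adjusted p = 0.525). Anaerobic respiration and fermentation genes were lower, 20 of 43 over all genes against 3 higher, and 22 against 3 when adjusted over the list alone. The list passed (median -0.41, adjusted p = 1.3e-05, and adjusted p = 0.31 with an estimated correlation). The nitrate transporter gene narK fell from 198 ± 25.8 to 33.9 ± 3.78 FPKM. The nitrate reductase genes narH and narI and the fumarate reductase gene frdD had log2 fold changes of -1.55 ± 0.14, -1.85 ± 0.16 and -1.07 ± 0.09.

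Iron uptake genes stood higher at 2 mg/L, 8 of 34 called in either adjustment and none lower (median 0.37, adjusted p = 0.00189, and adjusted p = 0.0756 with an estimated correlation). The ferric citrate receptor gene fecA rose from 30.5 ± 2.19 to 148 ± 9.33 FPKM (2.25 ± 0.13), fecB from 28.6 ± 9.49 to 91.7 ± 10.8 FPKM. The genes fecE and fhuF had log2 fold changes of 1.64 ± 0.31 and 0.72 ± 0.13. Acid resistance genes fell, 7 of 13 over all genes and 9 when adjusted over the list alone (median -0.50, adjusted p = 0.00101, and adjusted p = 0.31 with an estimated correlation). The glutamate-GABA antiporter gene gadC went from 8674 ± 847 to 2039 ± 46.5 FPKM. The genes slp, adiC and mdtF had log2 fold changes of -2.06 ± 0.20, -2.75 ± 0.27 and -0.80 ± 0.12. The regulator gene gadE did not pass (0.48 ± 0.49), but passed without control replicate 2 (1.08, adjusted p = 0.0357). In the envelope stress list, spy fell to 1259 ± 61.4 FPKM. The genes yccA, degP, cpxP and dsbA had log2 fold changes of -1.56 ± 0.09, -1.44 ± 0.12, -0.89 ± 0.19 and -0.47 ± 0.09, and the call of dsbA ended under quantile normalization (adjusted p = 0.0917). The list was lower, with 8 members lower and 1 higher in either adjustment (adjusted p = 0.038, and adjusted p = 0.683 with an estimated correlation). The call of this list ended without control replicate 1 (adjusted p = 0.0761), control replicate 3 (0.0816) or 2 mg/L replicate 3 (0.064). It also ended under quantile normalization (0.314), under a filter at a mean of 5 FPKM (0.0502) and on genes over 600 nt (0.107 on fragments and 0.129 on FPKM).

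Ribosomal protein genes stood higher at 2 mg/L, 9 of 54 higher and 1 lower over all genes, and 6 and 1 when adjusted over the list alone. The list passed (median 0.23, adjusted p = 0.00566, and adjusted p = 0.691 with an estimated correlation). The log2 fold changes of rpsQ, rpsN and rplS were 1.09 ± 0.25, 0.82 ± 0.17 and 0.77 ± 0.18, and rplO, the member that fell, had -0.49 ± 0.12. These genes are short, and over all genes of at most 300 nt the median log2 fold change at 2 mg/L was 0.43, against 0.07 at 20 µg/L. With the trend over coding length removed, the mean of the ribosomal list was -0.01 (adjusted p = 0.844) and rpsQ, rpsN and rplS did not pass. On genes over 600 nt alone the adjusted p of the list was 0.175 on fragments and 0.204 on FPKM. The call of rplO ended without control replicate 3 and without 2 mg/L replicate 2 or 3 (adjusted p up to 0.0835).

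Several of the named genes with the largest rises at 2 mg/L are short. The toxic peptide gene hokA, of 153 nt, was listed at 0 in every library of the control and of 20 µg/L and at 96.1 ± 11.1 FPKM at 2 mg/L (adjusted p = 5.7e-06). It is shorter than the mean fragment fitted in any library (179 to 197 nt), so its FPKM may rest on few fragments, which could not be counted. The cellulose synthesis gene bcsF and the curli gene csgE were listed at 0 in every control library and stood at 50 ± 9.26 and 9.11 ± 6.43 FPKM. The listed interval of bcsF runs from 29143 to 32578 on contig 26, so its value may depend on how reads were divided among the genes there. The cold shock family genes cspB and cspG went from 1246 ± 764 to 6284 ± 1314 and from 35.9 ± 46.7 to 518 ± 122 FPKM, and cspA had a log2 fold change of 1.74 ± 0.20. The nucleoid-associated modulator gene hha had 2.65 ± 0.45, the curli regulator gene csgD 2.78 ± 0.48, the outer membrane protease gene ompT 2.52 ± 0.46 and yhcN 2.42 ± 0.18. The genes gfcA and citD passed at 2.65 ± 0.84 and 2.53 ± 0.78. The calls of cspG and csgE each ended without 2 of the 2 mg/L libraries (replicates 1 and 3, and replicates 2 and 3, adjusted p up to 0.0581 and 0.0726). Those of gfcA and citD ended without 7 and 6 of the 9 libraries (adjusted p up to 0.141 and 0.127).

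Of the other fixed genes, soxS, a regulator of the superoxide response, rose from 549 ± 74.8 to 1429 ± 94.6 FPKM (1.39 ± 0.14, adjusted p = 2.0e-04). The genes lexA, ompF and ompA had log2 fold changes of 0.65 ± 0.14, 0.96 ± 0.16 and 0.49 ± 0.13, all passing. The catalase gene katG fell at -0.48 ± 0.08 and the sigma factor gene rpoS at -0.37 ± 0.12 (adjusted p = 0.0479). The calls of rpoS and ompA ended without 6 and 4 of the libraries (adjusted p up to 0.162 and 0.0786). With the 2 mg/L libraries averaged, lexA, ompF, ompA, katG and rpoS did not pass (adjusted p = 0.172, 0.0978, 0.245, 0.0836 and 0.311). For marA, acrB, tolC, ahpC, recA, umuD, ompC and pspA the log2 fold changes were 0.12, -0.05, 0.24, 0.08, 0.14, 1.32, -0.03 and 0.07, with no adjusted p below 0.299. Under quantile normalization tolC passed (adjusted p = 0.0286). The oxidative stress list did not pass, with 8 higher and 5 lower members of 29 (median 0.11), nor did SOS response (median 0.28, adjusted p = 0.0506), multidrug efflux (median 0.06) or general stress (median 0.07). Phospholipid synthesis, lipid A and LPS core, outer membrane proteins, heat shock, DNA uptake homologues, toxin-antitoxin genes and fimbriae, curli and exopolysaccharide did not pass either, with medians of -0.03, 0.07, 0.15, 0.06, 0.10, 0.47 and 0.10. Without nfsB, matched in error, the median of DNA uptake homologues was 0.12. In the list of fimbriae, curli and exopolysaccharide the test was negative while the median and mean were positive, with 8 members lower, among them wzb (-1.93), and 5 higher, among them csgD.

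In limma's test 1209 of the 4409 genes passed at 2 mg/L, 555 higher and 654 lower, of which 201 and 240 had a log2 fold change of at least 1. In 1205 of them the libraries of the conditions did not overlap, which a low p from the same libraries nearly requires. Over all genes the share was 44%, where chance gives 10%. The 3 libraries at 2 mg/L lay closer to each other than those of the other conditions, with a chi-square per degree of freedom of 1.74 to 1.92 between them against 6.45 to 14.8 between control libraries, and 351 genes passed when they were averaged into 1 sample. In that fit the calls of the named genes bcsF, cspB, cspG, csgE, csgD, gfcA, hha, citD and ompT ended (adjusted p up to 0.326, in citD). So did those of fecB, fecE, fhuF, mdtF, cpxP, dsbA, rpsN, rpsQ, rplS and rplO (adjusted p up to 0.218, in rplS).

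**Figure D3:**
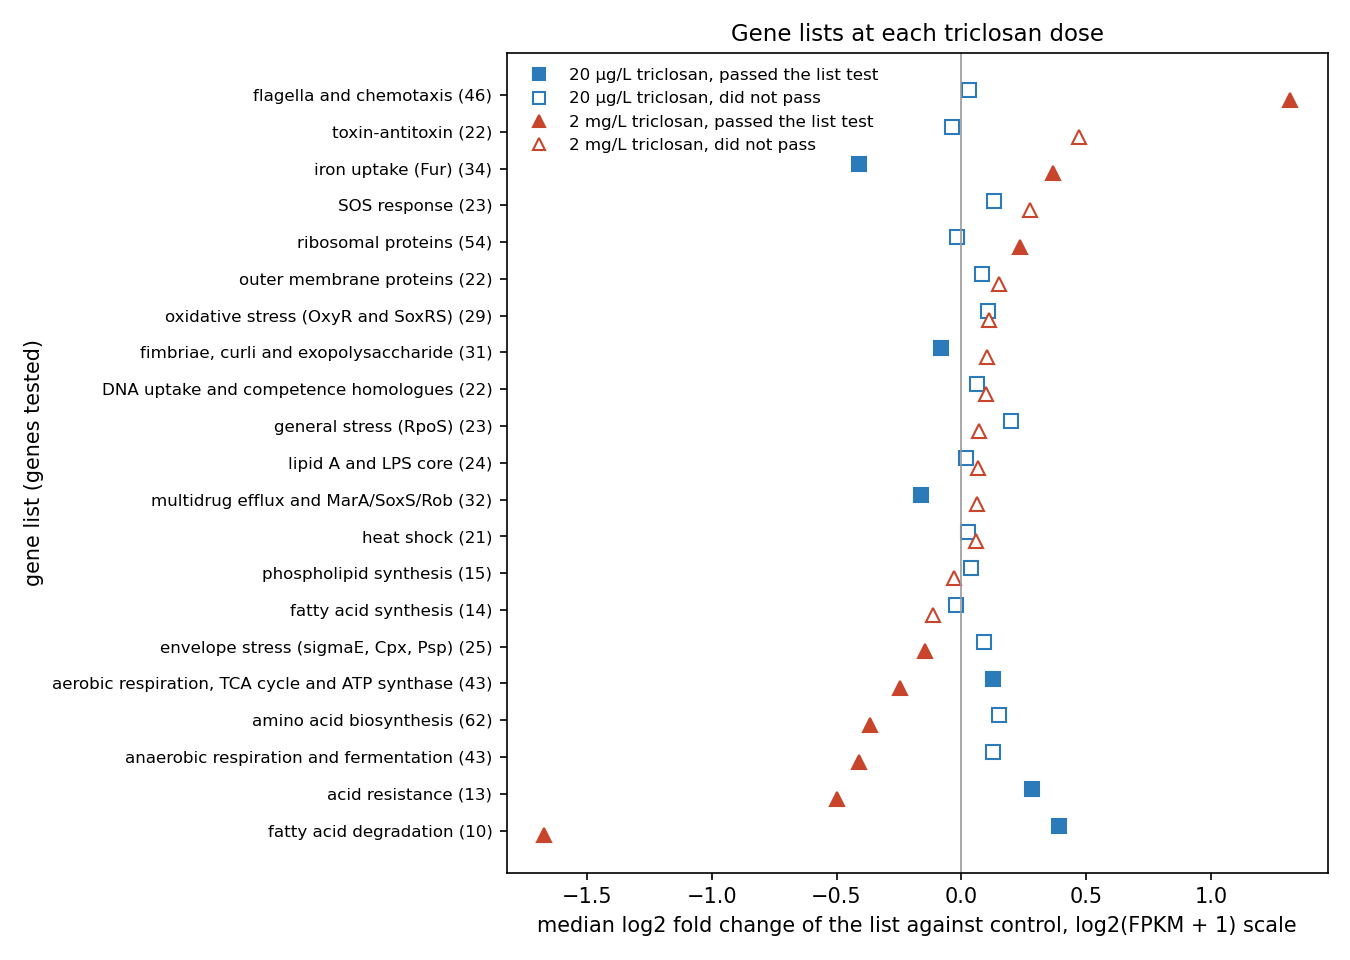
Median log2 fold change against control of each of the 21 gene lists tested (number of genes in brackets), at 20 µg/L (squares) and 2 mg/L (triangles), with filled symbols where the list test passed. The flagella list lies at 0.03 and 1.32, and the iron uptake list at -0.41 and 0.37.

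The doses were then compared with each other, since a gene that passes at 1 dose alone is not thereby shown to differ between them. Iron uptake genes were higher at 2 mg/L than at 20 µg/L, 20 of 34 over all genes and 25 when adjusted over the list alone. The list passed (median 0.81, camera adjusted p = 4.5e-08, and 0.00528 with an estimated correlation). In this comparison fecA had a log2 fold change of 2.65 ± 0.13, fecC 2.40 ± 0.34, fhuF 1.01 ± 0.13 and exbD 0.88 ± 0.10. Flagella and chemotaxis genes were higher, 27 over all genes and 32 when adjusted over the list alone (median 1.32, adjusted p = 1.0e-09, and 0.0045 with an estimated correlation). The values were 2.31 ± 0.25 for flgE, 2.32 ± 0.33 for flgF, 2.08 ± 0.27 for motA and 1.11 ± 0.11 for fliC. These were the only lists of the comparison to pass with an estimated correlation. Colanic acid genes were higher at 2 mg/L than at 20 µg/L, with wcaC at 1.80 ± 0.15, cpsB at 1.59 ± 0.17, wcaJ at 1.27 ± 0.17 and wcaB at 1.02 ± 0.17. Their list of fimbriae, curli and exopolysaccharide had 14 higher and 1 lower member, 15 and 2 when adjusted over the list alone (adjusted p = 9.4e-05, and adjusted p = 0.123 with an estimated correlation).

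Fatty acid degradation genes were lower at 2 mg/L than at 20 µg/L, 8 of 10 in either adjustment (median -2.08, adjusted p = 8.3e-08, and adjusted p = 0.17 with an estimated correlation). The log2 fold changes were -2.92 ± 0.16 for fadE and -2.77 ± 0.19 for fadB. Acid resistance genes were lower, 11 of 13 in either adjustment (median -1.01, adjusted p = 1.5e-06, and adjusted p = 0.147 with an estimated correlation), with adiC at -3.45 ± 0.27 and gadC at -2.28 ± 0.11. Anaerobic respiration genes were lower, 26 against 3 higher of 43, 28 against 3 when adjusted over the list alone (adjusted p = 1.0e-07, and adjusted p = 0.147 with an estimated correlation). The hydrogenase genes hyaA, hyaB and hyaC had log2 fold changes of -2.39, -2.28 and -2.23. Aerobic respiration genes were lower, 20 against 1 higher, 21 against 2 when adjusted over the list alone (median -0.30, adjusted p = 6.2e-05, and adjusted p = 0.497 with an estimated correlation). The gene sdhA had -1.82 ± 0.12, gltA -1.60 ± 0.13, icd -1.29 ± 0.12 and ndh 1.67 ± 0.09. The call of the aerobic list ended under quantile normalization (adjusted p = 0.398). Amino acid biosynthesis genes had 27 lower and 11 higher members, 28 and 14 when adjusted over the list alone (adjusted p = 1.9e-04, and adjusted p = 0.382 with an estimated correlation). Here trpE had -3.76 ± 0.17 and cysP -2.34 ± 0.08.

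The multidrug efflux list was higher at 2 mg/L than at 20 µg/L, 7 higher and 4 lower members in either adjustment (median 0.33, adjusted p = 0.0435, and adjusted p = 0.28 with an estimated correlation). The pump genes emrA and emrB had log2 fold changes of 0.93 ± 0.11 and 0.91 ± 0.10, inaA 1.67 ± 0.13 and soxS 1.51 ± 0.14, while marA and acrB did not pass (0.72 ± 0.27 and 0.22 ± 0.09). Without 20 µg/L replicate 2 marA passed (adjusted p = 0.0148), and acrB passed under quantile normalization (0.00463) and with only the compared libraries in the fit (0.0385). The call of that list ended without control replicate 2 (adjusted p = 0.0514), control replicate 3 (0.0605), 20 µg/L replicate 3 (0.106) or 2 mg/L replicate 3 (0.0612). It also ended under quantile normalization (0.149), on genes over 600 nt (0.115 on fragments and 0.124 on FPKM) and with the 2 mg/L libraries averaged (0.0614). Ribosomal protein genes were higher (adjusted p = 0.0842 on fragments and 0.105 on FPKM of genes over 600 nt), 6 over all genes and 2 when adjusted over the list alone, with rplS at 1.02 ± 0.18 and rpsB at 0.49 ± 0.10 (adjusted p = 0.00346, adjusted p = 0.648 with an estimated correlation, and adjusted p = 0.635 with the coding length trend removed). Envelope stress genes were lower, 7 in either adjustment, with cpxP at -1.16 ± 0.19, degP at -1.03 ± 0.12 and surA at -0.57 ± 0.11 (adjusted p = 0.0122, adjusted p = 0.508 with an estimated correlation, and adjusted p = 0.62 under quantile normalization). The call of surA ended under quantile normalization (adjusted p = 0.0992).

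The target gene fabI was lower at 2 mg/L than at 20 µg/L, 751 ± 53.3 against 1366 ± 142 FPKM (-0.86 ± 0.21, adjusted p = 0.0146), a call that ended without 20 µg/L replicate 3 or 2 mg/L replicate 1 (adjusted p up to 0.0534), under quantile normalization and with the 2 mg/L libraries averaged (adjusted p = 0.0529 and 0.224). Between the doses fabB differed by -1.08 ± 0.11, rpoS by -0.57 ± 0.12 and ompF by 0.81 ± 0.16, while recA (-0.01 ± 0.16), tolC and spy (-0.13 ± 0.12) did not pass. Of the named genes with the largest changes, zraP had -4.24 ± 0.44, aceA -3.83 ± 0.14, aceK -3.39 ± 0.14, trpD -3.63 ± 0.16 and mtr -3.54 ± 0.13. On the other side ybiJ had 2.93 ± 0.32, cspB 2.92 ± 0.37, ymdF 2.58 ± 0.19, opgC 2.49 ± 0.35 and mcbR 2.36 ± 0.47. The flagellar gene flgC passed at 2.68 ± 0.67, a call that ended without 2 mg/L replicate 1 or 2 (adjusted p up to 0.0672). In limma's test 1273 genes passed between the doses, 610 higher and 663 lower at 2 mg/L. In 1269 of them the libraries did not overlap, which a low p from the same libraries nearly requires. Over all genes the share was 50.4%, where chance gives 10%. When the 2 mg/L libraries were averaged into 1 sample, 391 genes passed. In that fit the calls of ompF, rpoS, fecC, cpxP, surA, rplS, rpsB, flgC, opgC and mcbR also ended (adjusted p up to 0.161, in mcbR).

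Of the 55 genes called at 20 µg/L, 36 were called in the same direction at 2 mg/L, among them wzb, gmd, argI, argD, spy, plaP and gatA, and 3 in the opposite direction, ycaO, ydfG and rhlE. Lower at both doses were 33 genes, where independent lists would share 7.42, and higher at both were 3, where independent lists would share 0.629. In simulated unchanged groups set against shared simulated controls, the overlap of calls reached 5 at most over 20 fits. No gene changed at either dose there, so this cannot show how much overlap shared controls add where many genes change. The difference between the doses passed for 39 of the 55: 34 genes that fell at 20 µg/L stood higher at 2 mg/L than at 20 µg/L, among them argI (0.85 ± 0.22), wzb and gmd. The genes pstS (-1.30 ± 0.11) and pstB (-1.06 ± 0.09) fell further. The 55 were picked with the same 20 µg/L libraries, which by itself favours a return toward the control. Both doses were also simulated at the same mean in every gene, with genes varying independently. Then 39 became 10.7 on average (3 to 19 over 100 draws) and 34 became 3.87 (0 to 10). These came out of 283 genes past the limit at 20 µg/L on average, against 55 in the data. Most of the 34 are colanic acid genes that moved together, and for such genes the simulated ranges are too narrow. Across all genes, which are not independent replicates, the log2 fold changes of the doses had a covariance of 0.283. Unchanged groups simulated against shared simulated controls gave 0.263 on average (0.158 to 0.383 over 100 draws), a difference of 0.0199. The covariance itself moved with the settings, to 0.465 without control replicate 3, 0.651 with a pseudocount of 0.1, and 0.0595 on fragments and 0.0463 on FPKM of genes over 600 nt. The simulated value was not computed again under these, so whether there is any excess under them is unknown. At the main setting the covariance lay within the simulated range, so no excess over shared controls is shown. The Pearson correlation was 0.407 against a simulated 0.582, and 57.8% of genes had the same sign against a simulated 71.6%. No gene changed in the simulated groups, so these values do not compare like with like. The 3 control libraries are too few to split, so part of any excess may come from the shared controls.

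The authors' deposited table holds a comparison of all 6 triclosan libraries, pooled over the doses, with the control. In it 132 loci had a q-value under 0.05, 72 higher and 60 lower with triclosan. Of these, 34 were called here at 20 µg/L and 125 at 2 mg/L, and 3 were called at neither dose.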

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

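The comparisons, tests, gene lists and most of the other settings tried were chosen before the data were examined. Chosen only after the results were seen were the tests of scaling for both gene groups, of chance highs in the controls, of shared controls, of equal doses, of fragment length and of values near 1 fragment, the other splits of the libraries, and all tests of short genes except that without control replicate 2. The passages below take the genes called at 20 µg/L that differed between the doses, and the lists called at both doses in opposite directions that also differed between them. Other lists that differed between the doses are described with the results.

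The colanic acid genes wzb, wzc, wcaA, wcaB, wcaC, wcaD, wcaE, wcaF and wcaJ of the fixed list had a median log2 fold change of -2.14 at 20 µg/L and -0.73 at 2 mg/L. Scaling of the libraries may be ruled out as the whole cause, since the weaker of the medians under median-of-ratios scaling and quantile normalization was -2.05, and so may any 1 library, since the weakest median with a library left out was -2.04. Control libraries that were high by chance would lower both doses alike, and the median between the doses was 1.27. These genes were taken up because they differed between the doses, so that value cannot decide whether chance highs in the controls played a part. A response to the lower dose that is partly absent at the higher dose stays open as a hypothesis, together with differences between cultures that the labels do not describe. Of the genes called at 20 µg/L, 39 differed between the doses by test, against 3 to 19 in simulations with equal doses that pick genes by the same limits. The simulated genes varied independently, and 283 of them passed the limit at 20 µg/L on average, against 55 in the data. Many of the 39 are colanic acid genes that moved together, so the range of 3 to 19 is too narrow for them. Among the 39, pstS and pstB fell further at 2 mg/L.

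The iron uptake list was lower at 20 µg/L and higher at 2 mg/L, where adjusted p = 0.0756 with an estimated correlation. Over all genes only entS was called at 20 µg/L and 8 members were called at 2 mg/L. No member was called in opposite directions at the doses, so the reversal is one of the list, not of single called genes. The median difference between the doses was 0.81, and that call held with an estimated correlation (adjusted p = 0.00528). Shared control libraries would move both doses the same way, and the median was -0.41 at 20 µg/L and 0.37 at 2 mg/L. The list was taken up here because its calls went in opposite directions, so these signs cannot decide whether shared controls played a part. Under median-of-ratios scaling and quantile normalization the median between the doses was at least 0.67, and 778 other genes in the list's middle range of levels (13.3 to 46 FPKM) had a median of 0.16 with a standard error of 0.043, well below that of the list. A first rule, which asked whether 0.16 differs from 0, left this test undecided, and the gap to the list was taken as deciding only after the value was seen. These values argue against scaling and against the low level of the genes as the whole cause. A dose-dependent difference in iron supply or demand may remain, and it was not tested.

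Fatty acid degradation genes differed between the doses by a median of -2.08 (adjusted p = 0.17 with an estimated correlation), with a higher list test at 20 µg/L and a lower at 2 mg/L (adjusted p = 0.411 and 0.31 with an estimated correlation). Acid resistance genes differed by -1.01 (adjusted p = 0.147 with an estimated correlation). Genes of aerobic respiration, the TCA cycle and ATP synthase differed by -0.30 (adjusted p = 0.497 with an estimated correlation and 0.398 under quantile normalization), and their call at 20 µg/L ended without control replicate 2 (adjusted p = 0.378).

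The 6 libraries of a comparison can be split in 10 ways, which are too few for a share under 0.05. For genes, the real split gave 55 at 20 µg/L, 1209 at 2 mg/L and 1273 between the doses, the highest other split 5, 3 and 3, and 1 of the 10 splits, the real one, gave as many in each. For gene lists, the real split gave 6, 9 and 11 and the highest other split 10, 8 and 10. At 20 µg/L, 5 of the 10 splits called at least as many lists, and in both other comparisons 1 did. So the number of lists called at 20 µg/L does not set the real split apart from regrouped libraries.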

How the results depend on the processing

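Leaving out each library in turn gave 34 to 62 genes at 20 µg/L, 894 to 1364 at 2 mg/L and 917 to 1529 between the doses, against 55, 1209 and 1273. The highest counts at 2 mg/L and between the doses came without control replicate 2. The count at 20 µg/L was 34 without 2 mg/L replicate 1 and 36 without control replicate 1, and the higher genes among them numbered 2 without 2 mg/L replicate 1 and 13 without control replicate 3, against 5. Gene lists ranged from 5 to 10, 7 to 10 and 10 to 11, with the 10 at 20 µg/L reached without control replicate 3. The covariance between the doses ranged from 0.267 to 0.465, the highest without control replicate 3, around 0.283.

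Stricter thresholds, by construction, gave fewer genes: 28, 712 and 744 at an adjusted p under 0.01, and 34, 441 and 465 with a log2 fold change of at least 1. With only the compared libraries in the fit, 31 genes passed at 20 µg/L. With the 2 mg/L libraries averaged as 1 sample, assumed to vary like the others, 28, 351 and 391 passed. On genes over 600 nt at 20 µg/L, 104 passed on fragments (26 higher and 78 lower) and 96 on FPKM, and the covariance was 0.0595 and 0.0463. With a pseudocount of 0.1 it was 0.651. With an estimated correlation 1, 1 and 2 lists passed. Under quantile normalization fabA, uncalled between the doses at -0.07, passed with a log2 fold change of 0.27. Apart from the thresholds the cause was not tested.

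With the replicate number as a block, 36 genes passed at 20 µg/L, 1135 at 2 mg/L and 1174 between the doses, and fabI passed at 2 mg/L (adjusted p = 0.0379). The numbers do not pair the samples: same-numbered libraries correlated at -0.109 to 0.0523 after the condition means were removed.

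Over all alternatives, the named genes gave 4598 values with the same call, 249 weaker, 41 stronger and 1 reversed, and the called lists 495 the same and 51 weaker. The same call under every alternative was kept by 39 of 55 named genes at 20 µg/L, 47 of 75 at 2 mg/L and 57 of 79 between the doses. Both tallies include named genes that were not called and stayed uncalled, and these 55 are not the 55 genes called at 20 µg/L. Named genes whose call at 20 µg/L ended under some alternative included cadB, gatA, ydfG, wcaF, rutB, mdfA and entS. Depth limits what low and short genes can show, with a median of 97 to 157 fragments on genes over 600 nt. The alternatives on genes over 600 nt, on the coding length trend and with the averaged libraries were chosen after the data were seen. The authors' q-values were not run as an alternative for each dose, since they pool the doses.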

Other observations

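The genes in this paragraph and the next were chosen after their values were seen. At 2 mg/L the phosphate uptake genes pstA, pstC and pstS had log2 fold changes of -2.40 ± 0.19, -2.29 ± 0.14 and -1.86 ± 0.11 against control, and their regulator genes phoB and phoR -1.58 ± 0.26 and -1.94 ± 0.17, all passing limma's test. At 20 µg/L pstA and pstC had -0.65 ± 0.19 and -0.70 ± 0.14 and did not pass (adjusted p = 0.193 and 0.057). The putrescine catabolism genes puuP and puuA fell at 2 mg/L, from 195 ± 30.9 to 33 ± 5.55 FPKM and from 891 ± 77.2 to 156 ± 11.3 FPKM. The aspartate carbamoyltransferase genes pyrB and pyrI had log2 fold changes of -1.99 ± 0.23 and -2.03 ± 0.30 at 2 mg/L.

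At 2 mg/L the leucine synthesis gene leuA went from 32.6 ± 7.53 to 126 ± 10.1 FPKM and leuB from 46.6 ± 4.8 to 147 ± 10.5 FPKM. At the same dose the regulator pair phoP and phoQ rose by 1.07 ± 0.14 and 1.33 ± 0.09, the sensor-regulator genes rstA and rstB by 1.62 ± 0.24 and 1.16 ± 0.34, and the glutaredoxin gene grxA by 2.35 ± 0.52. At 20 µg/L an unnamed pair of neighbouring loci, NJ74_RS01000, annotated as a polysaccharide export protein, and NJ74_RS00995, fell with log2 fold changes of -2.17 ± 0.23 and -1.84 ± 0.26.

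Genes of at most 300 nt stood higher at 2 mg/L, with a median log2 fold change of 0.43 over 559 genes and a standard error of 0.095, against 0.07 at 20 µg/L. The tests of fragment length and of values near 1 fragment were chosen after the pattern was seen. Control replicate 2 alone could not account for it, since the median without it was 0.48. For the rise over the control, shorter fragments in the 2 mg/L libraries stay open: their mean length was 193.1 nt against 190.0 nt in the controls. The control libraries ran from 179 to 197 nt, and the lowest was replicate 2. For the rise over 20 µg/L the values argue against shorter fragments as the cause. They do not cover other effects of fragment length on the FPKM of short genes. The 20 µg/L libraries measured 186 to 190 nt, all shorter than the 192 to 194 nt at 2 mg/L. Yet the short genes stood higher at 2 mg/L than at 20 µg/L, by a median of 0.296 with a standard error of 0.091. Values near 1 fragment may also account for part of it: the 238 genes of at most 300 nt with a mean of at least 100 FPKM had a median of 0.25 with a standard error of 0.138, which leaves this cause and a response of short genes open. No biological explanation was tested.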
